A study of Mus musculus with 6 samples.

How the data were processed

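Total RNA of the organ of Corti, the sensory epithelium of the cochlea with its hair cells and supporting cells, was profiled in mice at postnatal day 15. The animals had a mixed C57BL/6J-129/Sv background and were either homozygous for an inactivated Pjvk gene (Pjvk-/-, called knockout) or wild-type (Pjvk+/+). Each genotype had 3 samples, which makes 6 arrays. Per the labels' protocols, RNA was extracted with TRIzol and cleaned on RNeasy columns, and biotinylated cDNA was prepared from 100 ng of total RNA for an Affymetrix mouse gene ST array. The submitters' processing notes name the Affymetrix Expression Console, with no version. The deposited values were on a log2 scale, in 1 table of 35557 probe sets for the 6 arrays. The summarization and normalization behind them are not given in the sources used here. The arrays had nearly equal distributions, with medians from 6.66 to 6.69 and values between 2.02 and 14.08, so no further normalization was applied in the main analysis. The intensities of single probes were not analysed here.

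Probe sets were named through the platform annotation, which is dated and paired 21789 probe sets with 1 gene symbol. Another 1621 probe sets carried several symbols and 12147 were not listed in that annotation. None of these was named or used in the main analysis. Of the probe sets with 1 symbol, 21698 had a gene identifier that matched a table of mouse genes on the assembly GRCm38.p6, which updated the symbols and gave the order of genes along chromosomes. The table of values names no genome build, so no coordinates are printed. Where a gene had several probe sets, the probe set with the highest mean over the 6 arrays was kept, which left 19938 genes.

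Knockout and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over all genes. A gene was called at an adjusted p under 0.05. Every adjusted p of a gene given below comes from this fit unless another adjustment is named. The fit had 4 residual and 4.59 prior degrees of freedom, and the median standard error of a log2 fold change was 0.07. The number of arrays limits the precision. The labels do not say that the samples came from separate animals, and the sex-linked signals given below go with pools of both sexes. The p-values thus measure the spread between these samples, which may be technical. No pair of arrays held identical values throughout. With 3 arrays against 3, an exact permutation test cannot give a two-sided p below 0.1.

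The gene lists, the rule for naming genes and most alternatives were set before the data were examined. The 27 tested lists covered antioxidant and peroxisomal functions, cell types of the cochlea, cell types that a dissection could carry along, and stress, death, interferon, respiratory, cell cycle and sex-linked genes. They were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists and called at an adjusted p under 0.05. The estimated correlation, the rotation test fry and 10000 random lists matched on mean level served as comparisons. The random lists were drawn without regard to correlation between genes, so their range can be too narrow for a list of correlated genes. The genes adjusted over a list alone were counted as well. The 4 redox genes of the study's own account were described gene by gene.

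The named genes were chosen as follows. Pjvk and the 4 redox genes were always named. In each direction, up to 12 called genes with non-overlapping groups and the largest log2 fold change were named. Places left over were filled with genes at or above the median level, with non-overlapping groups and at least a 1.2-fold difference, by smallest unadjusted p. These are given as values, not as calls. For each list, up to 4 members with the smallest unadjusted p could be named. Predicted genes, clone names, olfactory and vomeronasal receptors and small RNAs were not named.

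The limma and camera steps were tested on simulated data with the spread of the real arrays and 19938 genes. The knockout and wild-type comparison recovered 39 of 50 genes changed 1.41-fold, 45 of 50 changed 1.68-fold, 49 of 50 changed 2-fold and 50 of 50 changed 2.83-fold, with 10 false calls among 193. The real comparison called 7 genes, and the many more calls in the simulation eased its adjustment. Changes of these sizes may thus be missed more often in the real data. No list was called when nothing changed, and the interferon list was called when it was lowered by 0.2 on the log2 scale. The simulated genes were drawn independently of each other, whereas the estimated correlation within the real interferon list was 0.18. The simulation therefore cannot tell how often camera calls a list of correlated genes falsely.

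The alternatives were a filter on dim genes at the 25th percentile or the median, quantile normalization, centring on the array medians, the mean of all probe sets of a gene, all probe sets, an intensity trend with robust priors, array weights, no moderation, the replicate number as a block, the level of Y-linked genes as a covariate, an adjusted p under 0.10, and leaving out each array. Cyclic loess was added after the data had been seen. The plots were drawn with matplotlib 3.10.9.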

Results

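The data set held 6 arrays of the organ of Corti from mice at postnatal day 15, 3 from Pjvk-/- and 3 from Pjvk+/+ animals. Pjvk encodes pejvakin, a protein of the gasdermin family whose loss causes deafness and which the study connects with peroxisomes and sound exposure. Correlations between arrays of a genotype over all probe sets ran from 0.9937 to 0.9940 in the knockout and from 0.9919 to 0.9932 in the wild-type, and between genotypes from 0.9913 to 0.9933, so that correlation alone did not set the genotypes apart. The first principal component held 34.2% of the variance and separated the genotypes, with the knockout arrays between -11.92 and -4.73 and the wild-type arrays between 1.69 and 13.05. The comparison of the genotypes asks which transcripts of the hearing organ differ when pejvakin is missing.

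The targeted gene itself had a lower signal in the knockout. The Pjvk probe set read 4.42, 4.36 and 4.21 on the log2 scale in the knockout arrays and 4.75, 5.06 and 4.96 in the wild-type arrays, so that all 3 knockout values lay below all 3 wild-type values. The difference was -0.59 with a standard error (SE) of 0.09, or 1.51-fold, and it did not pass the adjusted test (adjusted p = 0.105). An exact two-sided permutation test gave p = 0.1, the smallest this design allows. The signal was dim, at percentile 11.3 of the tested genes, and where the probes lie relative to the altered part of the gene is not known here, so the reading is a limited check of the labels.

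At an adjusted p under 0.05, 7 genes fell in the knockout and no gene rose. Dct, the dopachrome tautomerase of melanin synthesis, fell 3.64-fold, from 8.50 ± 0.29 in the wild-type to 6.64 ± 0.29 in the knockout (SD, n = 3 each, log2 scale). Cd59a, a membrane-anchored inhibitor of the complement attack complex, fell 2.12-fold, from 9.37 ± 0.03 to 8.28 ± 0.04. Ttn, which encodes the giant sarcomere protein titin, fell 1.93-fold, from 7.05 ± 0.03 to 6.10 ± 0.10. Their adjusted p-values were 0.0115 for Dct, 2.69e-04 for Cd59a and 0.00206 for Ttn. The other 4 genes fell by less. Qpct, a glutaminyl cyclase, fell 1.6-fold (SE of the log2 fold change 0.07, adjusted p = 0.0174), and H2-T24, a class I-like histocompatibility gene, 1.57-fold (SE 0.06, adjusted p = 0.00997). Lrrtm3, a synaptic leucine-rich repeat protein, fell 1.53-fold (SE 0.06, adjusted p = 0.0174), and Kcnj3, a G protein-gated potassium channel subunit, 1.52-fold (SE 0.07, adjusted p = 0.0397). In all 7 genes each knockout array lay below each wild-type array. The probe sets were 10422249 for Dct, 10474229 for Cd59a, 10483871 for Ttn, 10447056 for Qpct, 10450675 for H2-T24, 10369752 for Lrrtm3, 10472155 for Kcnj3 and 10473089 for Pjvk. Cd59a and H2-T24 have close relatives in the genome, and cross-hybridization between them was not assessed here, nor were variants of the parental strains under the probes of any of these genes, which can lower hybridization without a lower transcript level. In gene order, Ttn lies 3, Kcnj3 127 and Cd59a 356 genes from Pjvk on the same chromosome. Cd59b, a close relative of Cd59a that lies 355 genes from Pjvk, was lower too, at -0.56 (adjusted p = 0.0697). Whether the signals of Cd59a and Cd59b are separate was not assessed. Cd59b was mentioned after its value was seen and is not counted among the named genes below.

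**Figure D1:**
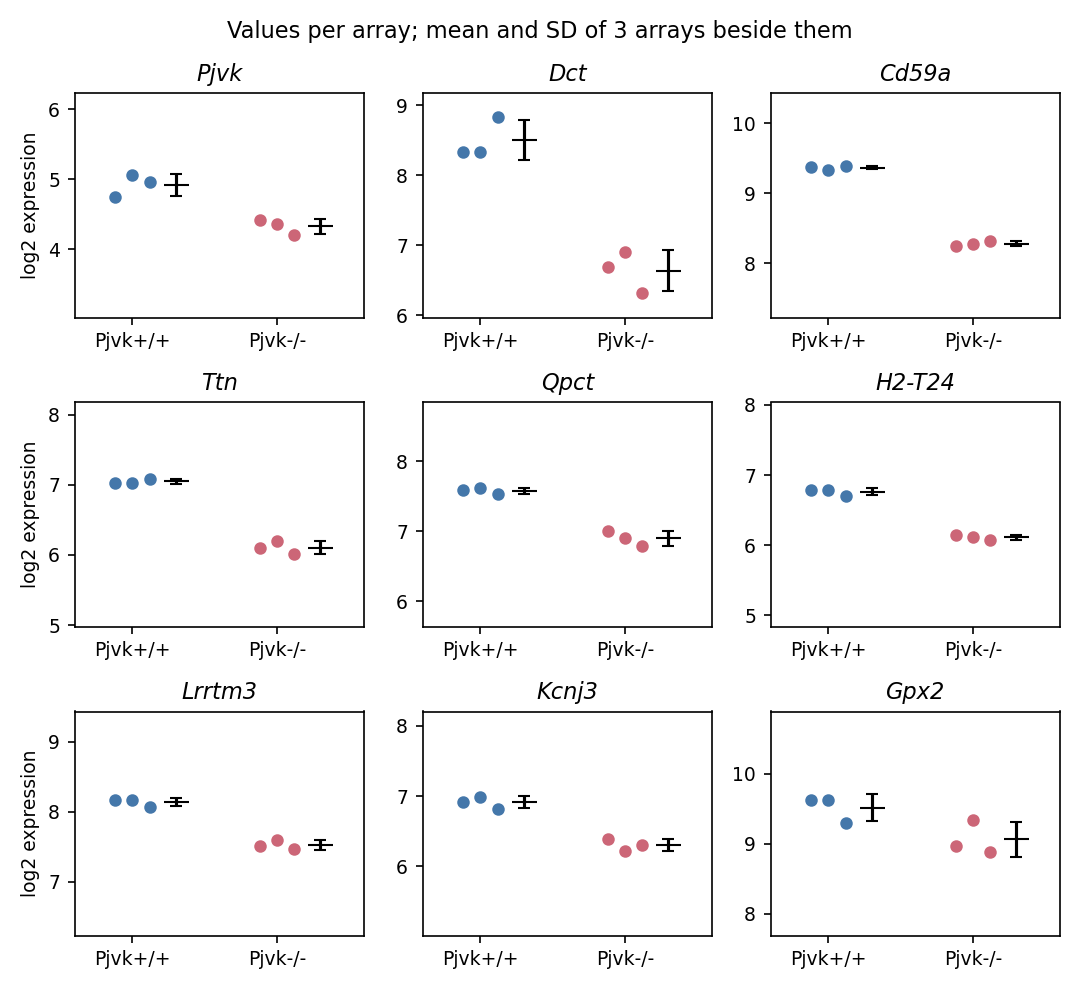
Log2 expression on each array for Pjvk, the 7 called genes and Gpx2, with 3 wild-type (blue) and 3 knockout (red) points per panel, a black bar for the mean and whiskers for the SD; every panel spans the same range of log2 units. In all panels except that of Gpx2 the knockout points lie below the wild-type points, with the widest gap for Dct, from 8.50 to 6.64.

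Without adjustment, 1144 genes were higher and 1327 lower at p under 0.05, 2471 in all, where 996.9 would be met by chance. That total was 1087 with the Y-linked level as a covariate and 1646 without knockout replicate 3. The direction of the genes at that p followed expression level. In decile 3, among the dimmer genes, 248 were higher and 44 lower, and in the brighter decile 8, 25 were higher and 215 lower. Part of the excess over chance may thus reflect a trend with level. Past 1.5-fold at that p were 22 genes, 5 higher and 17 lower, against 27 and 27 with the covariate and 16 and 28 without knockout replicate 2. The groups did not overlap for 3558 genes, 17.8% of those tested, against 10% by chance. Cd59a and Ttn stayed called whichever array was left out, Dct lost its call without knockout replicate 1 (adjusted p = 0.0655), wild-type replicate 1 (0.0798) or wild-type replicate 2 (0.0538), H2-T24 without knockout replicate 3 (0.0782), wild-type replicate 1 (0.0798) or wild-type replicate 2 (0.0584), Qpct with each array but knockout replicate 1 left out, Lrrtm3 with each but knockout replicate 2, Kcnj3 whichever array was left out, and all 7 with the Y-linked level as a covariate. The Y-linked levels of the genotypes did not overlap, so that covariate is largely confounded with the genotype. Calls lost with it need not mean smaller differences. Over its alternatives Cd59a lay between -1.12 and -1.04, Dct between -2.08 and -1.70, Ttn between -0.995 and -0.90 and the other called genes between -0.73 and -0.51. Pjvk was at -0.67 with the covariate (adjusted p = 0.910). With an intensity trend and robust priors, limma called 100 genes lower and 12 higher, and among genes at or above the median level it called 42 lower and 3 higher.

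Further genes were separated between the genotypes without passing the adjusted test. On the lower side, Tmem196 stood at 8.32 ± 0.21 in the knockout and 9.06 ± 0.09 in the wild-type. Cox8b, the muscle form of a cytochrome oxidase subunit, stood at 7.90 ± 0.18 and 8.64 ± 0.12, and Oasl2, an interferon-induced gene, at 6.99 ± 0.10 and 7.54 ± 0.05. Neb, which encodes the sarcomere protein nebulin, and Fam78a each had a log2 fold change of -0.47 (SE 0.06). The adjusted p-values of these 5 genes ran from 0.0534 for Neb to 0.0697 for Tmem196. Neb and Fam78a lie on the chromosome of Pjvk too, 133 and 268 genes away.

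On the higher side, Tectb, which encodes the tectorial membrane protein beta-tectorin, read 9.09 ± 0.10 in the knockout and 8.65 ± 0.04 in the wild-type (adjusted p = 0.0923). Cybrd1, a ferric reductase, differed by 0.45 (SE 0.07, adjusted p = 0.105) and Ccdc141 by 0.44 (SE 0.09, adjusted p = 0.177). The 9 remaining genes that the rule named were C2cd4a at 0.41, Btbd17 at 0.38, Gdf10 at 0.34, Tmem91 at 0.31, Cpne6 and Myo18b at 0.30, Col6a1 and Kcnj13 at 0.29 and Ranbp3l at 0.27 on the log2 scale. All had an adjusted p between 0.177 and 0.225.

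The study's published account, as recalled, singled out 4 redox-related genes on these samples, which were therefore looked at first among the antioxidant genes. Dct is one of them and fell, as given above. Gpx2, a glutathione peroxidase, read 9.06 ± 0.25 in the knockout and 9.51 ± 0.19 in the wild-type, a difference of -0.45 (SE 0.13, adjusted p = 0.276, exact permutation p = 0.2), which was -0.15 with the Y-linked level as a covariate. Mpv17, an inner mitochondrial membrane protein, differed by -0.07 (SE 0.08, adjusted p = 0.698; -0.24 with that covariate) and Ppia, which encodes cyclophilin A, by -0.05 (SE 0.06, adjusted p = 0.744). Their exact permutation p-values were 0.5 and 0.3. All 7 probe sets of Ppia lay between -0.11 and -0.04. Adjusted over the list alone, Dct and Gpx2 passed, 2 of 4, against 1 of 4 over all genes, and the first count is not independent evidence because the list was chosen on these samples.

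Antioxidant genes as a group lay lower in the knockout. Of 41 measured members 35 were lower and 6 higher, with a median log2 fold change of -0.08, and the list was called (camera adjusted p = 0.00376; adjusted p = 0.326 with an estimated correlation). No single member passed, either over all genes or adjusted over the list alone. Nfe2l2, which encodes the transcription factor NRF2 and lies 9 genes from Pjvk, differed by -0.24 (SE 0.06). Nqo1 differed by -0.24 (SE 0.08), and the cystine transporter gene Slc7a11 went the other way at 0.24 (SE 0.07). With the Y-linked level as a covariate Nqo1 was at -0.07 and Slc7a11 at 0.37, and without knockout replicate 3 Nqo1 was at -0.16. Random lists of the same levels had medians between -0.07 and -0.01 in 95% of draws, and the list lay at percentile 0.29 of them. The list was no longer called with the Y-linked level as a covariate (median -0.05, adjusted p = 0.171), above the median level (0.0752) or with cyclic loess (0.0928), which was chosen after the data had been seen.

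Genes for the making of peroxisomes were called lower, by no more than lists of the same level. Of 17 measured members 16 were lower, with a median of -0.06 (camera adjusted p = 0.0429; adjusted p = 0.326 with an estimated correlation; fry adjusted p = 0.0451). The median lay inside the range of matched random lists, -0.08 to 0.01, and no member passed over all genes or adjusted over the list alone. Pex11a, a peroxisome proliferation gene, differed by -0.27 (SE 0.07), Pex13 by -0.13 (SE 0.06) and Pex14 by -0.14 (SE 0.07). The enzymes and membrane proteins of peroxisomes were not called, with a median of -0.04 over 46 members, 30 lower and 16 higher (camera adjusted p = 0.462). Phyh, which acts in the alpha-oxidation of branched fatty acids, differed by -0.17 (SE 0.07) and Far2, which makes fatty alcohols, by 0.22 (SE 0.09). The call of the biogenesis list was lost without knockout replicate 1 (adjusted p = 0.0765), knockout replicate 3 (0.0913), wild-type replicate 1 (0.0567) or wild-type replicate 3 (0.109). It was lost too with quantile normalization (0.171), cyclic loess (0.281), the filters at the 25th percentile (0.130) and the median level (0.475) or the Y-linked covariate (0.136). Its median did not shrink with the filters (-0.06 each) or the covariate (-0.07), and was -0.04 with quantile normalization and with cyclic loess.

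Interferon-stimulated genes had the largest median shift among the 27 tested lists in the main analysis. Of 21 measured members 19 were lower in the knockout, 15 of them adjusted over the list alone and none over all genes. The median log2 fold change was -0.27, and the list was called by camera (adjusted p = 2.26e-10; adjusted p = 0.326 with an estimated correlation) and by fry (adjusted p = 0.0451). Ifit3, which encodes an interferon-induced tetratricopeptide protein, was lower 2.06-fold, from 6.86 ± 0.37 in the wild-type to 5.82 ± 0.31 in the knockout (log2 fold change -1.04, and -0.36 with the Y-linked level as a covariate). Oasl2 differed by -0.55 (SE 0.07), Ifi27l2a by -0.45 (SE 0.10) and Irf9, a component of the transcription factor that responds to type I interferon, by -0.25 (SE 0.05). All of these 4 passed adjusted over the list alone. The mean of the list, as a deviation from the mean of all arrays, was -0.16 in each knockout array and 0.24, 0.22 and 0.02 in the wild-type arrays. Among 10000 random lists of the same levels none had a median as low, with 95% of them between -0.05 and 0.07. That range ignores the estimated correlation within the list, 0.18, and can be too narrow. Y-linked transcripts were lower in the knockout too, and with their level as a covariate the list median was -0.11 (camera adjusted p = 0.00577). The medians of the skeletal muscle list (0.16) and the respiratory chain list (-0.12) were then larger in size.

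**Figure D2:**
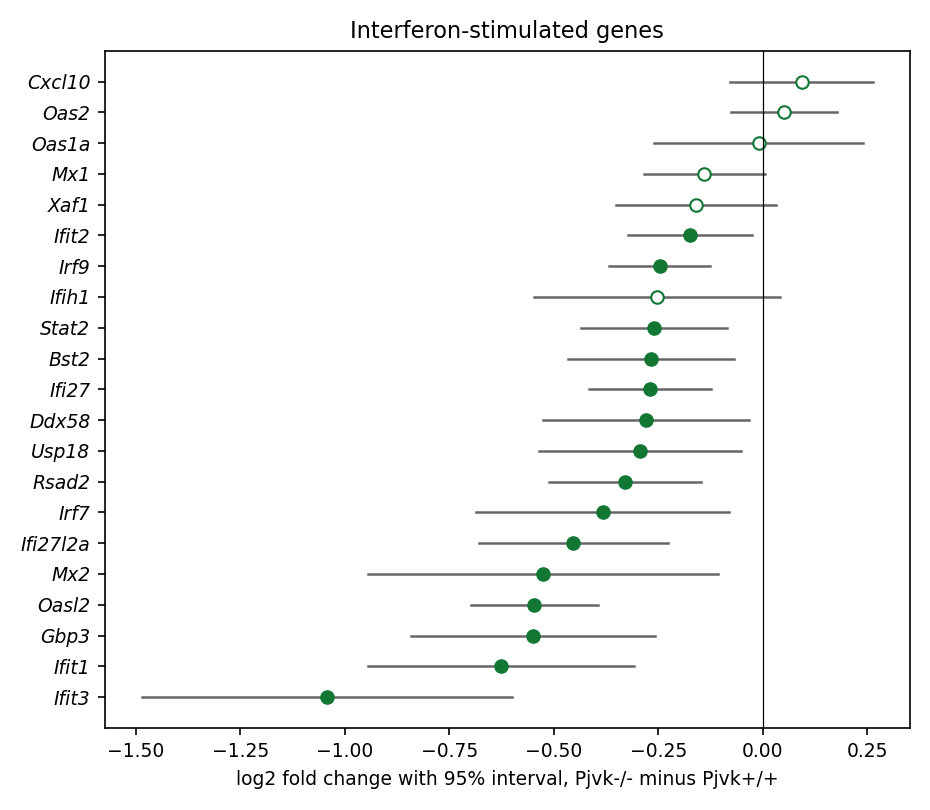
Log2 fold change, knockout minus wild-type, of the 21 measured interferon-stimulated genes with 95% intervals from limma; filled points passed when adjusted over the list alone. The 19 lower genes lie left of 0, with Ifit3 at -1.04, and 15 points are filled.

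Nuclear genes of the respiratory chain lay lower almost throughout. Of 40 measured members 39 were lower, 17 of them at an unadjusted p under 0.05, and none passed over all genes or adjusted over the list alone. The median was -0.12 (camera adjusted p = 8.65e-10; adjusted p = 0.326 with an estimated correlation; fry adjusted p = 0.0451). Ndufs4 and Ndufb9 of complex I differed by -0.25 (SE 0.06) and -0.22 (SE 0.07), Cox7a2 of complex IV by -0.18 (SE 0.05) and Atp5g1 of the ATP synthase by -0.26 (SE 0.07). Bright genes in general lay slightly lower in the knockout and dim genes slightly higher, with a median of -0.04 in expression decile 10 and 0.07 in decile 3. Random lists of the same levels as the respiratory list had medians between -0.07 and -0.02 in 95% of draws, and none of 10000 was as low as the list. Here too the range ignores the estimated correlation within the list, 0.16.

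Blood vessel genes lay lower as well. Of 21 measured members 19 were lower, with a median of -0.11 (camera adjusted p = 1.45e-04; adjusted p = 0.326 with an estimated correlation). Acta2 and Myh11, contractile genes of smooth muscle and pericytes, differed by -0.38 (SE 0.07) and -0.31 (SE 0.07) and were the 2 members that passed adjusted over the list alone. Abcc9, a pericyte gene, and Flt1, an endothelial receptor, each differed by -0.22 (SE 0.07). The list lay at percentile 0.18 of matched random lists. With the Y-linked level as a covariate it was not called (adjusted p = 0.0964), although its median stayed at -0.095. Myh11 was then at -0.17 and Abcc9 at -0.07, while Acta2 stayed between -0.44 and -0.34 over all alternatives. Autophagy genes were lower in 24 of 25 members, with a median of -0.07 (camera adjusted p = 0.0119; adjusted p = 0.528 with an estimated correlation), and none passed adjusted over the list alone. The median lay inside the range of matched random lists, -0.08 to -0.01. Map1lc3b and Atg4b, which act in the lipid conjugation of autophagosomes, differed by -0.17 (SE 0.06) and -0.14 (SE 0.05). The autophagy call was lost without wild-type replicate 1 (adjusted p = 0.10), with quantile normalization (0.157), with cyclic loess (0.281), above the median level (0.258) and with the Y-linked covariate (median -0.03, adjusted p = 0.507).

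Neither the hair cell list nor the supporting cell list was called, although fry found changes of members in either direction in both (adjusted p = 2.31e-05 and 0.0107). Hair cell markers had a median of 0.04 over 31 members, 17 higher and 14 lower (camera adjusted p = 0.328), above the range of matched random lists, -0.06 to 0.03. Adjusted over the list alone, Lmo7, a protein of the actin-rich cuticular plate, was lower at -0.48 (SE 0.08). Xirp2, an actin-binding protein of stereocilia, was higher at 0.25 (SE 0.06). Xirp2 is a muscle gene too and lies 80 genes from Pjvk. The skeletal muscle list had a median of 0.12, with 17 members higher and 8 lower. The Xirp2 difference therefore cannot be assigned to hair cells, because carried-along muscle may supply part of it. Tmc1, a subunit of the mechanotransduction channel, differed by 0.22 (SE 0.06) and Ptprq, a stereocilia phosphatase, by 0.39 (SE 0.11). With 1 array left out Ptprq ran from 0.24 to 0.475. Supporting cell markers had a median of 0.03 over 29 members, 16 higher (camera adjusted p = 0.329), also above the matched range, -0.07 to -0.003, with Tectb the 1 member that passed adjusted over the list alone. Otog, another tectorial membrane gene, differed by 0.21 (SE 0.07) and Prox1, a transcription factor of supporting cells and neurons, by -0.21 (SE 0.06).

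Neurons and glia were likewise not called. Spiral ganglion and other neuronal genes had a median of -0.03 over 29 members, 17 lower (camera adjusted p = 0.329, and 0.00558 by fry for changes in either direction). At an unadjusted p under 0.05, 4 of the 29 were lower and 0 higher, near the share over all genes, 2471 of 19938. Slc17a6, a vesicular glutamate transporter, differed by -0.28 (SE 0.08). Schwann cell and myelin genes had a median of -0.02 over 21 members, 11 lower (camera adjusted p = 0.727). In both lists no member passed adjusted over the list alone. Fibrocyte and mesenchyme genes had a median of -0.01 and a test that pointed upward over 25 members, 14 lower (camera adjusted p = 0.679). Col1a1 differed by 0.41 (SE 0.16) and Slc26a4, which encodes the anion exchanger pendrin, by -0.28 (SE 0.10). With 1 array left out Col1a1 ran from 0.25 to 0.58. The 20 genes of ion channels and transporters for endolymph and hair cells had a median of -0.04 (camera adjusted p = 0.460; 0.00129 by fry for changes in either direction).

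Genes of the stria vascularis, the secretory tissue of the lateral wall, moved both ways. The list of 25 was not called, with a median of -0.01 and a mean of -0.13 (camera adjusted p = 0.215; 0.00174 by fry for changes in either direction). Adjusted over the list alone, 5 members were lower and 1 higher. Besides Dct, Met differed by -0.32 (SE 0.06), Gpnmb by -0.46 (SE 0.09), Esrrb, a regulator of strial marginal cells, by -0.47 (SE 0.10) and Kcne1, a potassium channel subunit of the same cells, by -0.31 (SE 0.10). Kcnj13, an inward rectifier potassium channel, was the higher member at 0.29 (SE 0.06).

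Skeletal muscle genes, which a dissection can carry along, were split. Of 25 measured members 17 were higher and 8 lower, with a median of 0.12 (camera adjusted p = 0.0124; adjusted p = 0.575 with an estimated correlation), at percentile 99.92 of matched random lists. Adjusted over the list alone 4 were higher and 2 lower. Myh4, a fast myosin heavy chain, and Tnnc2, fast troponin C, were higher at 0.35 (SE 0.07) and 0.39 (SE 0.09), while Ttn and Neb, giant proteins of the same sarcomeres, were the lower pair. Without knockout replicate 3 the median was 0.21 (adjusted p = 2.19e-04), and the list was not called without knockout replicate 2 (median 0.05, adjusted p = 0.20) or wild-type replicate 3 (adjusted p = 0.0637), nor with quantile normalization (0.112) or cyclic loess (0.102).

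Other tissue markers differed little. Neutrophil and lymphocyte genes were higher in 18 of 23 members, with a median of 0.08 (camera adjusted p = 0.0221; adjusted p = 0.528 with an estimated correlation), and proliferation genes in 20 of 24, with a median of 0.08 (camera adjusted p = 0.0420; adjusted p = 0.326 with an estimated correlation). No member of either list passed adjusted over the list alone, and both lists were dim. Their medians lay inside the ranges of matched random lists, which reached 0.11 and 0.098. The neutrophil call was lost without knockout replicate 3 (adjusted p = 0.183) or wild-type replicate 1 (0.0864) or 2 (0.0605), and the proliferation call without knockout replicate 1 (0.0923) or wild-type replicate 1 (0.0864) or 2 (0.0605), with the mean of probe sets (0.0760), the filter at the 25th percentile (0.0913) and the Y-linked covariate (0.348), and both with quantile normalization (0.271 each) and cyclic loess (0.402 each). With the Y-linked level as a covariate the neutrophil median turned to -0.03. Macrophage genes had a median of -0.01 and a test that pointed upward over 25 members (camera adjusted p = 0.901), and the complement gene C1qc differed by -0.15 (SE 0.06). Bone and cartilage genes had a median of 0.04 over 19 members (camera adjusted p = 0.166) and red blood cell genes a median of 0.01 over 9 (camera adjusted p = 0.495).

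**Figure D3:**
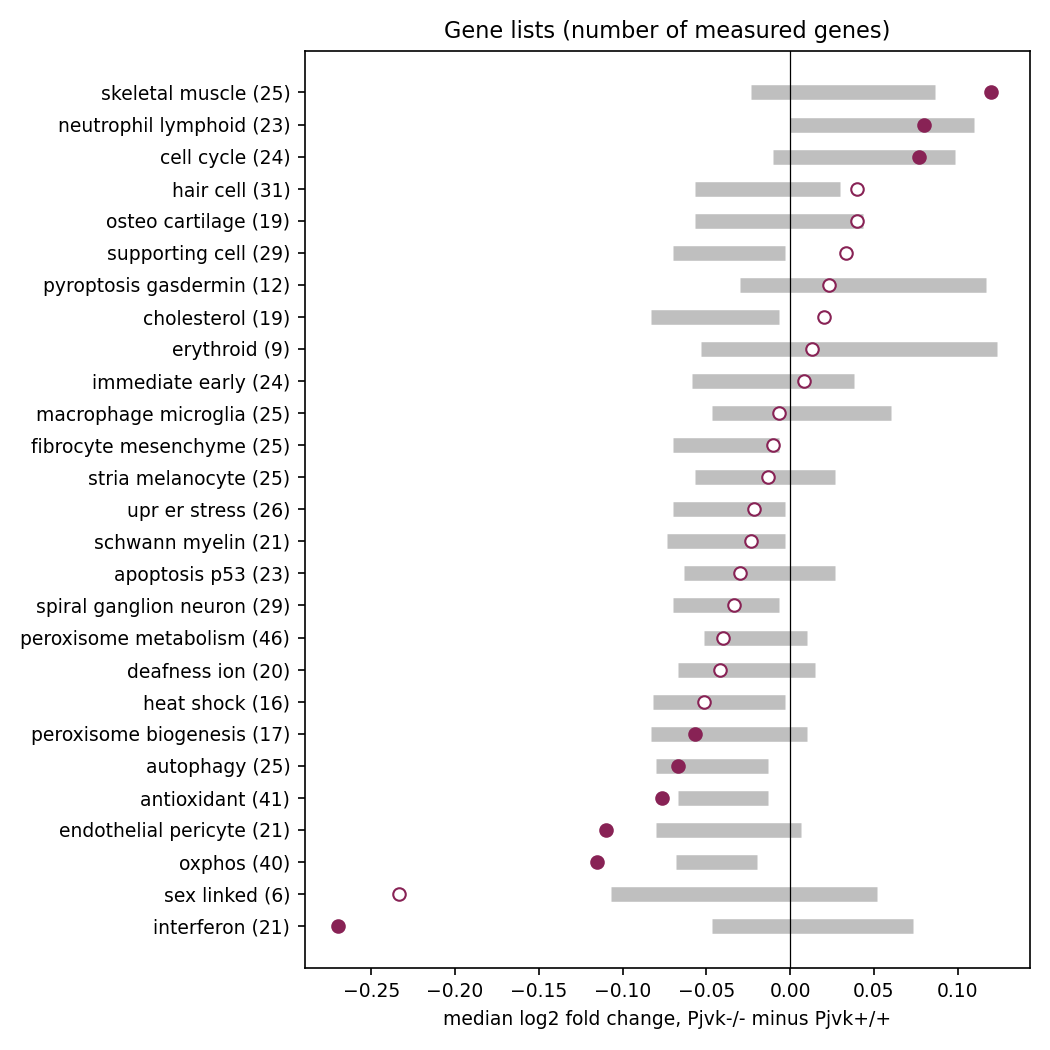
Median log2 fold change, knockout minus wild-type, of the 27 tested gene lists, with the number of measured genes in brackets; filled points were called by camera at the preset correlation, and grey bars span 95% of 10000 random lists matched on mean level. The interferon list lies farthest from its bar at -0.27, and no list was called with an estimated correlation.

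Stress and death pathways were not called by camera. The unfolded protein response had a median of -0.02 over 26 members (camera adjusted p = 0.377), with Asns, an asparagine synthetase, at -0.18 (SE 0.06). Cytosolic chaperones had a median of -0.05 over 16 (camera adjusted p = 0.0589). Apoptosis genes and targets of p53 had a median of -0.03 over 23 (camera adjusted p = 0.678), among which Pmaip1 and Gadd45a differed by 0.33 (SE 0.09) and 0.21 (SE 0.06) and Fas by -0.21 (SE 0.05). The gasdermin family and inflammasome genes had a median of 0.02 over 12 (camera adjusted p = 0.679). Immediate early genes had a median of 0.01, a mean of -0.01 and a test that pointed upward over 24 (camera adjusted p = 0.968). Zfp36, an mRNA decay factor, was lower among them adjusted over the list alone at -0.34 (SE 0.07), and Jun differed by 0.29 (SE 0.08). By fry, members changed in either direction among apoptosis genes (adjusted p = 0.00380), gasdermin and inflammasome genes (0.00262) and immediate early genes (0.00129). Cholesterol synthesis genes had a median of 0.02 over 19 (camera adjusted p = 0.329), above the matched range, -0.08 to -0.007.

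The sexes of the animals are not given, and the arrays differed in sex-linked transcripts. The mean of the measured Y-linked genes lay between 7.39 and 7.58 on the knockout arrays and between 7.65 and 8.05 on the wild-type arrays, without overlap. Kdm5d differed by -0.40 (SE 0.11), Uty by -0.34 (SE 0.10) and Eif2s3y by -0.33 (SE 0.12), and all 3 were lower adjusted over the list alone. Xist, expressed from the inactive X chromosome of females, differed by 0.28 (SE 0.14). With 1 array left out Xist ran from 0.18 to 0.46 and Eif2s3y from -0.43 to -0.21. Xist read between 9.36 and 9.96 on the 6 arrays, at percentile 94.2 of the tested genes, and Eif2s3y lay at percentile 71.2. Each array thus held female and male signals, which goes with RNA pooled from both sexes, although this was not checked further. The list of 6 was not called (median -0.23, camera adjusted p = 0.0636), and no member passed over all genes.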

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

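The alternative of cyclic loess was chosen after the data had been seen, and the others were set beforehand. The counts of called genes, 7 lower and 0 higher, moved with the setting in both directions. They were 18 and 2 among genes at or above the 25th percentile of level, 42 and 3 at or above the median, 100 and 12 with an intensity trend and robust priors, and 20 and 2 at an adjusted p under 0.10. Centring the arrays gave 18 lower genes. The count fell to 1, Cd59a, without moderation of the variances and with every probe set tested, and to 0 with the Y-linked level as a covariate. All 7 genes were kept with the 25th percentile filter, quantile normalization, centring, the mean of probe sets, the trend, array weights and cyclic loess. Ttn, H2-T24 and Kcnj3 lie below the median level and were not tested under the median filter. Leaving out 1 array gave 2 to 6 lower and 0 to 1 higher genes. The filters test fewer genes, which eases the adjustment. The Y-linked covariate is largely confounded with the genotype, so calls lost with it need not mean smaller differences. For the remaining settings the cause was not tested.

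The count past 1.5-fold, 22, became 10 above the median level, 195 with every probe set and 54 with the Y-linked covariate, and ran from 20 to 44 with 1 array left out (44 without knockout replicate 2, 34 without wild-type replicate 3). Pjvk differed by -0.59 and passed only with the trend and robust priors (adjusted p = 0.0207, within a range from 0.0207 to 0.910 over its alternatives). It lay between -0.68 and -0.53 with 1 array left out. The 9 called lists became 5 above the median level, 4 with quantile normalization, 3 with the Y-linked covariate, 3 with cyclic loess, 3 with fry (15 when fry tested for changes in either direction), 0 with an estimated correlation and 5 to 11 with 1 array left out. The interferon and respiratory chain lists were called under each alternative in which the lists were tested at the preset correlation; the lists were not run without moderation or with every probe set. Of the uncalled lists, supporting cells (0.0160) and cholesterol synthesis (0.00725) passed above the median level, both with a test that pointed upward. The median of the supporting cell list was then -0.01, against -0.04 over all genes tested there, so it was higher only relative to other bright genes. Cytosolic chaperones passed with the mean of probe sets (0.0367) and with the trend (0.0296). With 1 array left out, chaperones passed without knockout replicate 2 (0.0144) or wild-type replicate 2 (0.0497), cholesterol synthesis (0.0150) and bone and cartilage (0.0393) without knockout replicate 2, and fibrocytes (0.0483) without knockout replicate 3. The sex-linked list passed with the block (0.0371). The bracketed values of these lists are adjusted p-values. With the Y-linked covariate Uty turned to 0.019, Eif2s3y to 0.046, Xist to -0.15 and the neutrophil list to -0.027. That covariate moved 33 of 83 named genes by over 1.5 times, among them Gpx2 to -0.15, Ifit3 to -0.36 and Ccdc141 to 0.70, where no other setting moved more than 7. Of the 18 uncalled lists, most with medians near 0, the median changed sign in 6 with the covariate, in 5 with cyclic loess, in 2 with quantile normalization, in 1 with centring, in 4 of 15 above the median level and in 0 to 3 with 1 array left out. Mpv17 lay between -0.12 and 0.0033 with 1 array left out, the latter without wild-type replicate 3. Because the Y-linked levels of the genotypes did not overlap, shifts with that covariate cannot be told apart from the genotype. For the shifts in other settings the cause was not tested.

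The replicate numbers gave no clear sign of pairing the samples, although so few arrays cannot exclude it. Deviations of same-numbered arrays correlated at 0.08, 0.02 and -0.01, and 3 of the 6 arrays (knockout replicates 1 and 2 and wild-type replicate 1) correlated best with their own number. With the replicate number as a block, 1 gene was called lower and 10 lists were called. The dim signal of Pjvk limits its check.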

Other observations

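The tests of explanations below were chosen after the results were seen, except that the fits with 1 array left out and with the Y-linked covariate had been planned as alternatives. Dct differed by -1.86, and the other pigment genes of the stria list differed by less and not all in the same direction. Gpnmb, a protein of pigment granules, was lower at -0.46 (SE 0.09) adjusted over that list alone. Of the rest, named after their values were seen, Tyr differed by -0.31 (SE 0.13), Slc45a2 by -0.24 (SE 0.11), Mlana by -0.10 (SE 0.06), Tyrp1 by 0.09 (SE 0.07), Pmel by 0.14 (SE 0.10) and Oca2 by 0.15 (SE 0.06). With the Y-linked covariate Tyr was at -0.55, Slc45a2 at -0.48, Mlana at -0.18, Tyrp1 at 0.20 and Pmel at 0.24, and with 1 array left out Tyr ran from -0.42 to -0.18, Slc45a2 from -0.38 to -0.16, Mlana from -0.13 to -0.06, Pmel from 0.06 to 0.26 and Tyrp1 from 0.027 to 0.14. None of these 6 passed over all genes or adjusted over the list alone.

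With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 7 called genes, and the highest of the other splits gave 0. Unadjusted p-values under 0.05 numbered 2471 in the real split and at most 1574 in the others. The real split gave 22 genes past 1.5-fold against at most 11, and 9 called lists against at most 5. In each case 1 of the 10 splits, the real one, reached the real value.

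The genes around Pjvk in gene order held more differences than most stretches of the genome. Among the 200 nearest genes 14 had an unadjusted p under 0.01, among them Prkra 1 gene away (-0.27), Ttn 3 away (-0.95), Ccdc141 4 away (0.44) and Nfe2l2 9 away (-0.24). As many were held by 3 of 85 other windows (median 6, highest 16). The whole chromosome held 1731 genes besides Pjvk, against 18124 on the others. It held 3 of the 7 called genes and 6 of the 20 smallest p-values, more than its share of genes. Over all its genes 3.93% reached an unadjusted p under 0.01, against 3.33% on the others. A shortage of muscle in the knockout dissections is argued against for Ttn and Neb, since the other 23 skeletal muscle genes had a median of 0.14, with 17 higher and 6 lower. The 95% bootstrap interval of that median, 0.01 to 0.23, came from resampling genes and does not measure the spread between arrays. With 1 array left out the median of the whole muscle list stayed between 0.05 and 0.21. Cox8b, a muscle gene outside that list, went the other way at -0.74. Of the 14 genes near Pjvk 6 were higher, among them the muscle genes Klhl41 (0.26), Chrna1 (0.39) and Xirp2 (0.25), so that carried-along muscle may supply part of the count. A linked chromosome segment from the other parental strain and an effect of the mutation on adjoining genes alone both stay open, because the window sizes differ without the 10 nearest genes on each side: 10 of 180 genes remained, a count that 8 of 85 windows reached, against 7 of 80 in the smaller window, a count that 6 of 186 reached. An effect of missing pejvakin stays open as untested, and Prkra, Klhl41 and Chrna1 were named after their values were seen.

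The interferon-stimulated genes were lower together. The tendency of bright genes to be lower does not apply to this list, which had a median level of only 6.50. Random lists matched on level had a median of 0.01, and the list lay at percentile 0 of them. Fewer macrophages are argued against, since the macrophage list had a median of -0.0067 against -0.27 for the interferon list. Its mean deviation ran from -0.06 to 0.04 over the knockout arrays and from -0.004 to 0.02 over the wild-type arrays. The 95% bootstrap intervals of the medians, -0.08 to 0.07 and -0.38 to -0.25, came from resampling genes and do not measure the spread between arrays. A different mix of sexes may contribute and cannot be told apart from the genotype, because the Y-linked levels of the genotypes did not overlap and the list median shrank to -0.11 with that level as a covariate. The genotype itself and the parental strain at interferon genes stay open as untested.

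The respiratory chain genes were lower together by a small amount. The tendency of bright genes to be lower does not account for all of it, with the list at percentile 0 of matched random lists. No single array accounts for it either, since the median stayed at -0.10 or lower whichever array was left out (-0.0967 at the highest). A different mix of sexes may contribute and cannot be told apart from the genotype, although the median was -0.12 with the Y-linked level as a covariate. The genotype itself and the parental strain stay open as untested.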
